A study of Penicillium decumbens with 4 samples.

How the data were processed

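The data were digital gene expression tag profiles of mycelial RNA from Penicillium decumbens, with 1 library for each combination of strain (wild type 114-2 or brlA deletion) and medium (liquid or solid). Per the labels' protocols, messenger RNA was captured on oligo(dT) beads and made into cDNA, which was cut with NlaIII at CATG. MmeI then released a tag of CATG plus 17 bases, and the tags were amplified by PCR, selected by size on a gel and sequenced. Per the labels, the authors trimmed adaptors and discarded tags of low quality, tags seen once and tags of another length, and the rest are called clean tags. The composition of the 2 media, the background of the deletion strain and any further culture replicates are not given in the sources used here.

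The deposited tables give, for each distinct clean tag, its count (copy number) and its TPM. The lowest deposited count was 2 in each library, and all listed tags were 21 nt long and began with CATG. The deposited TPM is the authors' scaling of each count to a common total of clean tags. Recomputed from the counts, it differed by at most 0.00500 TPM, which is rounding. Per the labels, the authors also matched tags to predicted transcripts and summed them by gene. Those gene values were not used here, and no reference genome was used, so each value refers to a tag and not to a gene. A gene with several CATG sites, incomplete digestion or alternative poly(A) sites can give several tags, and near-identical genes can share one.

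Copies summed to between 5839769 and 6023076 per library, so that depths differed little. With 1 library per group there was no test across tags and no p-value. Tags were compared by size: the TPM had to differ at least 4-fold and the higher library had to hold at least 20 copies. An unlisted tag was set to a floor of 3 copies, and its fold is then a lower bound. The named tags had copies in all 4 libraries. These limits, the comparisons, the correlation of the deletion effects and the rule for naming items were fixed before the data were examined. They had been written for genes and were applied to tags, and the 24 gene lists planned with them were not matched to tags. Intervals of ratios are exact conditional binomial intervals, those of TPM are exact Poisson intervals and those of shares are Clopper-Pearson intervals, all at 95%. They cover counting error only, leaving out differences between cultures and the PCR copies of single molecules.

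Named tags were, for each comparison, the 2 highest and the 2 lowest among those past the size limits, ranked by the bound of the 95% interval of the ratio nearest to 1. The most abundant tags, and the 3 tags that differed in opposite directions between media, were added after their values had been seen. So were the counts above and below both neighbouring libraries, and the comparison of the medium effects between strains. The groups of tags ending in at least 6 A, with at most 4 or with at least 11 G or C among 17 bases were also added then. For each such group the median log2 ratio was set against 10000 random lists of the same size, matched on deciles of level. Such lists show the spread among tags of the same 2 libraries only. A shift of the group throughout a library, whatever its source, would also fall outside them. The overlap expected of independent lists was the product of both counts divided by the number of tags tested in both comparisons, each count being taken among those tags only.

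The size rule was tested on simulated libraries drawn from the real means and depths, with 50 tags changed at each of 4 fold sizes per comparison. For the deletion strain against the wild type in liquid medium, run on 20496 tags, it recovered 92% of the tags changed 6-fold and 100% of those changed 8-fold. Among unchanged tags 7 were called there, and 4% of those changed 3-fold. For solid against liquid medium in the deletion strain, run on 20951 tags, it recovered 96% at 6-fold and called 5 unchanged tags. Only counting error was simulated, and the changed tags were picked among those with a mean of at least 20 copies. These values therefore give no rate of false calls from differences between cultures.

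Alternatives were TMM scaling with edgeR 4.0.16 in R 4.3.3, used for scaling factors only, median-of-ratios scaling, other minimum copies, a 2-fold limit, a limit on the counting interval and other floors. Added after the data were seen were a floor of 5 copies, leaving out tags 1 base away from a tag with at least 50 times their copies, merging A-ended tags by site, merging tags that share their first 14 bases, a correction for G and C content and leaving out A-ended tags. TMM scaling moved the median log2 ratio of tags with at least 50 copies in both libraries by more than 0.1 in 2 comparisons. In the wild type it went from 0.04 to -0.08 for solid against liquid medium, and in the deletion strain from 0.15 to 0.03. Ratios in the report are on the scale of clean-tag totals. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.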

Results

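Transcript tags were counted in mycelia of the filamentous fungus Penicillium decumbens, which secretes enzymes that degrade plant cell walls. The wild type strain 114-2 and a strain with brlA deleted were each grown in liquid and on solid medium. In related moulds brlA encodes a zinc finger transcription factor that starts the formation of conidiophores, the stalks that bear asexual spores. Conidia had been grown for 12 h in 2% glucose, and RNA was taken 48 h after the mycelia were moved to fresh medium. Each of the 4 groups held 1 library, so no difference described here has a replicate check. Each tag was a 21-nt sequence that began at a CATG site, and it was identified by its sequence alone, with no gene name. The brlA transcript was not analysed here, and the strain labels were therefore not checked against the deleted gene. The composition of the media and the background of the deletion strain were not given. A difference between strains or media may therefore not stem from brlA or from surface growth.

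The libraries held 5944107 clean tag copies in the wild type in liquid medium, 5839769 in the wild type on solid medium, 6023076 in the deletion strain in liquid medium and 6002816 in the deletion strain on solid medium. These copies fell on 87565, 90411, 96315 and 90753 distinct tags in the same order. A single copy corresponded to between 0.166 and 0.171 TPM, the unit in which copies are scaled to a common total of clean tags. Tags with at least 20 copies numbered between 18108 and 19380 per library and carried between 93.7% and 94.2% of the copies. Over the 4 libraries together 163180 distinct tags were listed, of which 45342 were listed in all 4 and 71353 in 1 library only. The shared tags carried at least 96.6% of the copies of each library.

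A single tag, CATGCAAATATTAATGAAATC, was the most abundant in 3 of the libraries. It reached 36265 TPM in the wild type in liquid medium, 24454 on solid medium, 21766 in the deletion strain in liquid medium and 15735 on solid medium. In the deletion strain on solid medium the most abundant tag was CATGTCCGTTTTTGTTCGAAA, with 26398 TPM, against 5301 TPM in the wild type in liquid medium, 7002 TPM in the wild type on solid medium and 9425 TPM in the deletion strain in liquid medium. These tags were chosen after their values were seen. Of the 100 most abundant tags of each library, 43 were common to all 4. The wild type libraries shared 73 of them, the deletion libraries 68, the liquid libraries 67 and the solid libraries 57.

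Across 41993 tags with at least 20 copies over the 4 libraries, log2 TPM correlated most closely between the wild type libraries (Pearson r = 0.90). It correlated less between the liquid libraries (r = 0.86), the solid libraries (r = 0.84) and the deletion libraries (r = 0.80). Pairs that share neither strain nor medium were about as close as the deletion pair. The wild type in liquid with the deletion strain on solid medium gave r = 0.83, and the wild type on solid with the deletion strain in liquid medium gave r = 0.80. These correlations are across tags, which are not independent replicates. Among tags with at least 50 copies in both members of a pair, the standard deviation of the log2 ratio was 0.66 for the wild type pair. It was 0.78 for the liquid pair, 0.88 for the solid pair and 0.93 for the deletion pair. The pairs that share neither strain nor medium gave 0.92 and 0.93, in the order above. Counting error alone would have given 0.17 in each of these pairs.

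The effect of deleting brlA in liquid culture was asked first. More tags were higher than lower in the deletion strain, 1413 against 642, out of 22009 tags tested. The tag CATGTTCTTTCAGAGAAAAAA stood at 80.7 TPM in the deletion strain and 0.336 TPM in the wild type, a 240-fold ratio with a 95% counting interval of 66.0 to 1986. CATGTTCTTTCAGAAAAAAAA, which shares its first 14 bases with that tag and differs from it at the next base only, had 511 copies against 6. On the lower side, CATGAAATTACTTCTTCGGGA was 70.0-fold lower in the deletion strain (95% interval 49.98 to 101), at 5.64 TPM against 395 TPM. CATGGAGCGTCCTACAAAAAG was 99.6-fold lower (38.6 to 367), with 4 copies against 393. Intervals here and below are exact and cover counting error only.

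The 1413 higher tags carried 4.86% of the copies in the deletion strain and 0.847% in the wild type, and the 642 lower tags carried 0.611% and 3.84%. Differences of at least 16-fold were found for 69 higher and 44 lower tags. Differing tags made up 11.9% of the tags under 10 TPM, 6.97% of those from 10 to 100 TPM, 5.26% of those from 100 to 1000 TPM and 9.43% of the 159 tags at 1000 TPM and over. Tags rich in G and C, with at least 11 of the 17 bases after CATG, stood higher in the deletion strain, with a median log2 ratio of 0.41 over 2083 tags. The medians of 10000 random lists matched on level ranged from -0.02 to 0.10 (central 95%). Tags with at most 4 G or C, those ending in a run of A left out, had a median of -0.25 over 1869 tags, below every random list. On solid medium the corresponding medians were -0.07, within the random range, and 0.03, above its random range of -0.14 to -0.02, and the former turned to 0.02 with TMM and with median-of-ratios scaling. These groups were defined after the data had been seen.

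**Figure D1:**
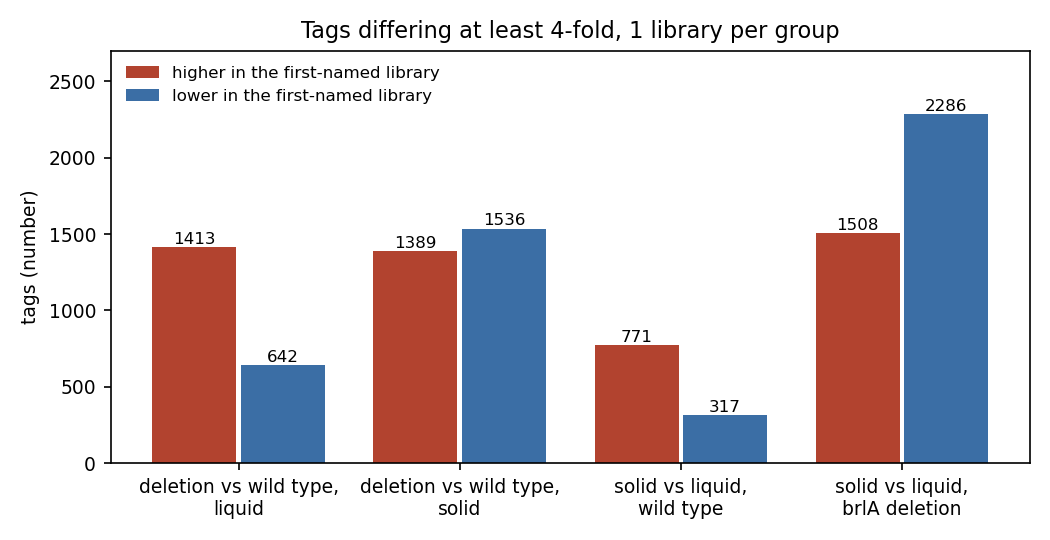
Number of tags (vertical axis) that differed at least 4-fold between 2 libraries, with at least 20 copies in the higher one, for the 4 comparisons, each bar counting the tags higher (red) or lower (blue) in the first-named library. The deletion strain on solid against liquid medium gave the most, 1508 higher and 2286 lower, and the wild type the fewest, 771 and 317.

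On solid medium, where the same question was asked of surface growth, 1389 tags were higher and 1536 lower in the deletion strain than in the wild type, among 22581 tested. The tag CATGTCTGAGAAATCAATTTC was 177-fold higher in the deletion strain (109 to 310), at 484 TPM against 2.74 TPM. CATGGGGAGAAAGGAATGAAT was 242-fold higher (103 to 746), with 1242 copies against 5. CATGAACAGTTAAAAAAAAAA was 502-fold lower in the deletion strain (244 to 1250), at 1.17 TPM against 586 TPM in the wild type. CATGGATGAATAGTTTAATTA was 161-fold lower (91.9 to 312), with 12 copies against 1878.

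Both of the latter tags were also lower in the deletion strain in liquid medium, where they had 2 and 10 copies against 238 and 364 in the wild type. The higher tags on solid medium took 5.95% of the copies in the deletion strain and 0.787% in the wild type, and the lower tags took 1.08% and 7.21%. Of the higher tags 146, and of the lower tags 163, differed by at least 16-fold. Tags that end in a run of at least 6 A, as tags that reach the poly(A) tail do, made up 16.8% of the lower tags, 5.54% of the higher ones and 12.0% of all tags tested. Their median log2 ratio was -0.59 over 2711 tags, below every one of 10000 matched random lists. In liquid medium their median was 0.09, within the random range of -0.01 to 0.10. The random lists show the spread among tags only, and a shift from library preparation would fall outside them too. Which direction held the majority depended on the setting, since 47.5% of the differing tags were higher with clean-tag totals, 52.4% with trimmed mean of M values (TMM) scaling and 52.7% with median-of-ratios scaling. The share was 50.6% with at least 50 copies and 50.7% without A-ended tags.

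**Figure D2:**
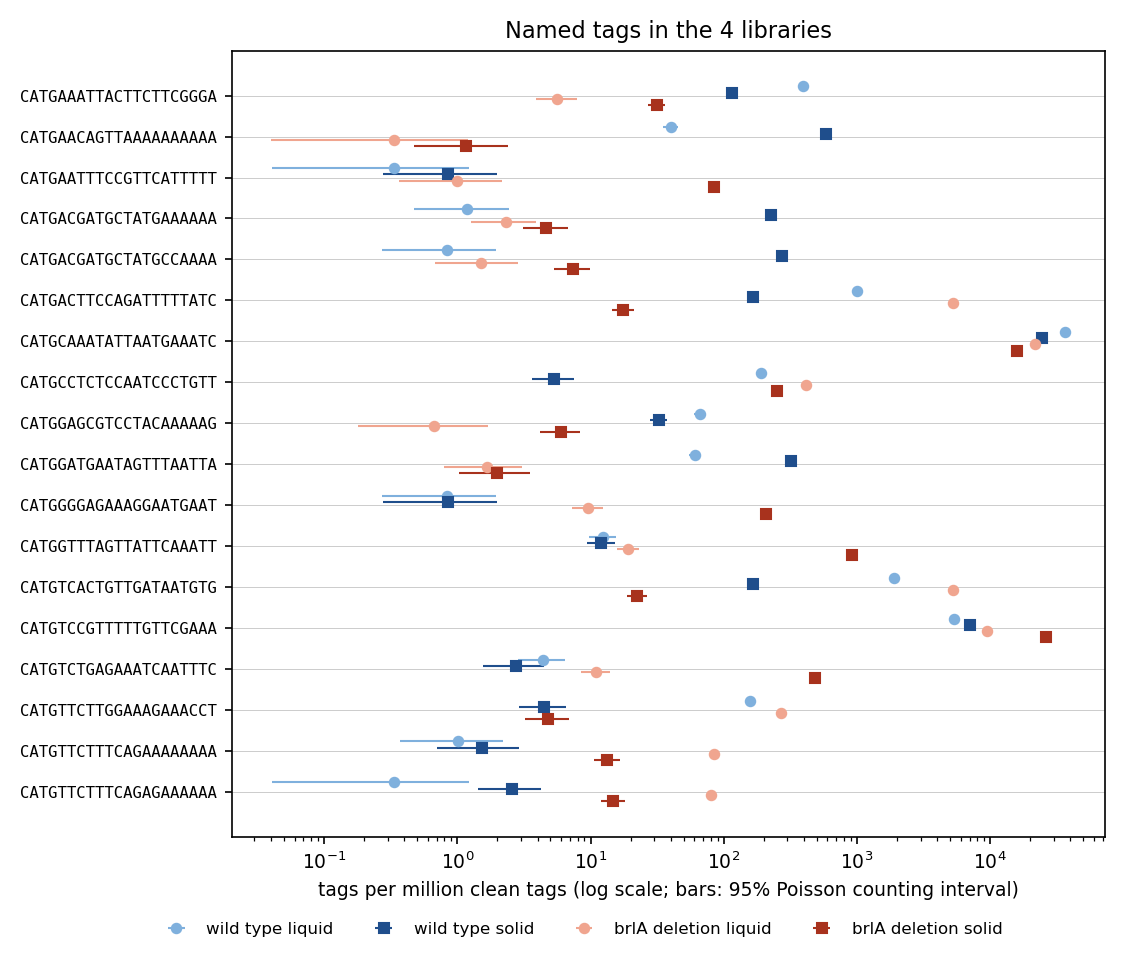
Level of each named tag in TPM (horizontal log axis) in the wild type (blue) and the brlA deletion strain (red), in liquid (circles) and on solid medium (squares), with bars for the 95% Poisson counting interval of 1 library each. CATGACGATGCTATGCCAAAA stands at 272 TPM in the wild type on solid medium and at 7.33 TPM or below in the other libraries.

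The response of the wild type to the medium was the smallest of the 4 comparisons. On solid medium 771 tags were higher and 317 lower than in liquid medium, together 5.12% of the 21252 tested. The tag CATGACGATGCTATGCCAAAA was 323-fold higher on solid medium (138 to 998), at 272 TPM against 0.841 TPM. CATGACGATGCTATGAAAAAA, which shares its first 15 bases with it, was 193-fold higher (93.5 to 481). In the deletion strain on solid medium these tags had 44 and 28 copies, against 1589 and 1328 in the wild type. CATGCCTCTCCAATCCCTGTT was 35.9-fold lower on solid medium (25.1 to 53.1), with 31 copies against 1132, and CATGTTCTTGGAAAGAAACCT was 35.4-fold lower (24.0 to 54.5), with 26 against 937.

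The higher tags carried 3.31% of the copies on solid medium and 0.459% in liquid medium. Of them 71 differed by at least 16-fold, as did 14 of the lower tags. Tags ending in a run of A made up 16.6% of the higher tags and 3.79% of the lower ones, against 12.2% of all tags tested. Over 2587 such tags the median log2 ratio of solid to liquid medium was 0.68, above each of 10000 matched random lists. Their share of all copies was 12.7% in the wild type on solid medium (95% exact binomial interval 12.6% to 12.7%). It was 8.66% in the wild type in liquid medium, 9.23% in the deletion strain in liquid medium and 9.13% on solid medium. The median of 0.68 and that of -0.59 between strains on solid medium share the wild type solid library.

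In the deletion strain the media differed at more tags than in any other comparison. On solid medium 1508 tags were higher and 2286 lower than in liquid medium, out of 23038 tested (16.5%). The tag CATGGTTTAGTTATTCAAATT was 47.4-fold higher on solid medium (39.4 to 57.5), at 913 TPM against 19.3 TPM, and its wild type levels were 12.0 TPM on solid and 12.4 TPM in liquid medium. CATGAATTTCCGTTCATTTTT was 85.3-fold higher (38.9 to 233), with 510 copies against 6. The tag CATGACTTCCAGATTTTTATC was 296-fold lower on solid medium (244 to 361), at 17.7 TPM against 5220 TPM. CATGTCACTGTTGATAATGTG was 233-fold lower (197 to 279), at 22.3 TPM against 5210 TPM.

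Both of these lower tags were also lower on solid medium in the wild type, by 5.94-fold and 11.4-fold. In the deletion strain the tags lower on solid medium had carried 9.93% of the copies in liquid medium and 0.953% on solid medium, and 432 of them were unlisted on solid medium. The higher tags carried 5.63% of the copies on solid medium and 0.917% in liquid medium. Differences of at least 16-fold numbered 309 among the lower tags and 98 among the higher ones. Tags rich in G and C were lower on solid medium, with a median log2 ratio of -0.32 over 2183 tags, and tags poor in them were higher, with a median of 0.39 over 1944 tags. These medians lay below and above all 10000 matched random lists, respectively, and they share the deletion strain's liquid library with the shifts seen between strains in liquid medium. The lower majority held at 4-fold and turned at 2-fold, where 5078 tags were higher and 4775 lower, and the median log2 ratio of all tags tested was 0.12.

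The effects of the deletion in the 2 media, which share no library, were then set side by side. Of the tags tested in both media, 148 were higher and 192 lower in the deletion strain in each medium, where independent lists would have given 20.5 and 26.1. A further 42 were higher in liquid and lower on solid medium, against 28.9 for independent lists, and 3 were lower in liquid and higher on solid medium, against 18.4. Those 3, given because they are few and not by rank, were CATGTTCCTGCTGCCCTGTTG, CATGTCCACCTAGCAAGGCTG and CATGTTCCTCAGCAGTGGCAT, with log2 ratios of -2.16, -2.02 and -2.24 in liquid medium and 2.16, 2.29 and 2.16 on solid medium. Across the 41993 tags the log2 ratios in the 2 media correlated weakly (Pearson r = 0.24, Spearman rho = 0.22, across tags). Many of these tags have few copies, and among the fewer tags with at least 50 copies in each of the 4 libraries r was 0.327. Tags with at least 20 copies in both libraries of one strain and unlisted in both of the other numbered 11 for the wild type and 9 for the deletion strain. An unlisted tag had at most 1 copy, because tags seen once had been removed.

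**Figure D3:**
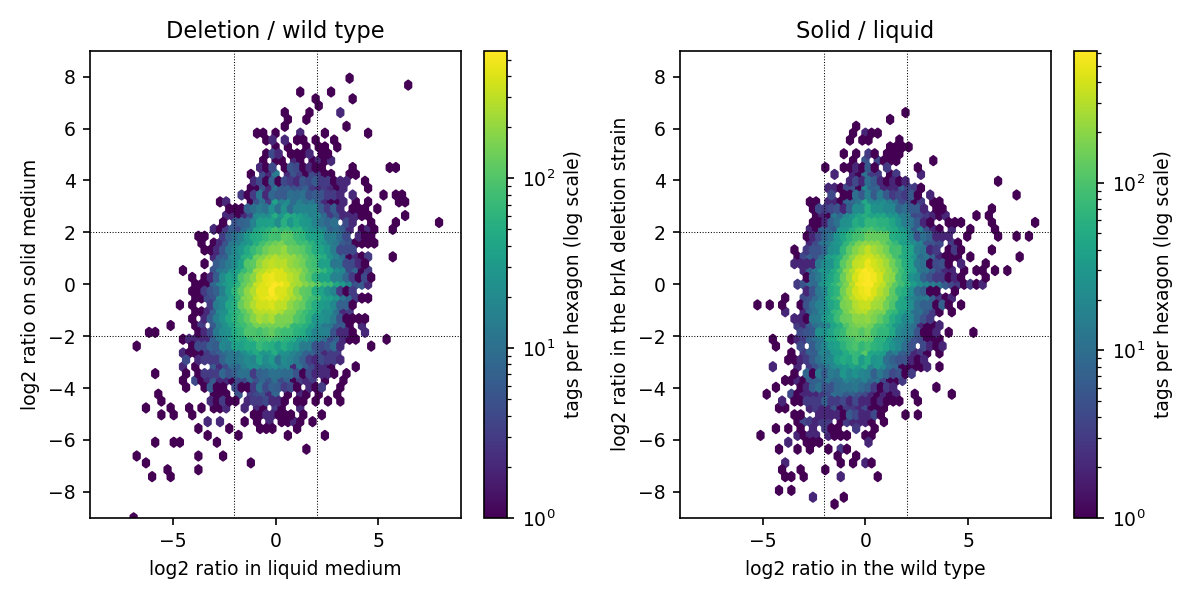
Each hexagon counts tags (colour, log scale) by their log2 ratio in 2 comparisons, the deletion strain over the wild type in liquid and on solid medium (left) and solid over liquid medium in the wild type and the deletion strain (right), with dotted lines at 4-fold. The clouds tilt upward only slightly, with Pearson r of 0.24 on the left and 0.23 on the right.

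The responses to the medium in the 2 strains were compared in the same way and also share no library. Tags higher on solid medium in both strains numbered 80, and tags lower in both 155, against 16.1 and 15.8 for independent lists. Tags that differed in opposite directions numbered 24 and 6, against 23.5 and 10.8. The correlation of the log2 ratios was 0.23 (Spearman rho 0.20), and 0.282 among the fewer tags with at least 50 copies in each of the 4 libraries. Tags higher on solid medium in the wild type had a median log2 ratio of 2.62 there and 0.56 in the deletion strain, and 10.4% of them passed the same limits in the deletion strain. Tags lower on solid medium in the wild type had medians of -2.56 and -1.995, and 48.9% of them were also lower in the deletion strain. A smaller ratio in the second strain is partly built into this selection, because the tags were picked by their ratio in the wild type.

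Tags that stood at least 4-fold above both the other medium of the same strain and the other strain on the same medium were counted for each library, a count added after the data had been seen. They numbered 759 for the deletion strain in liquid medium, 599 for the deletion strain on solid medium, 327 for the wild type on solid medium and 36 for the wild type in liquid medium. Independent lists would have given 157, 103, 59.0 and 10.6. Tags below both neighbours numbered 348 for the deletion strain on solid medium, 111 for the deletion strain in liquid medium, 79 for the wild type in liquid medium and 59 for the wild type on solid medium. The wild type tags that were higher on solid medium included CATGACGATGCTATGCCAAAA, and 42.4% of them were at least 4-fold lower in the deletion strain on solid medium. The 2 comparisons behind each count share a library, and part of the excess may come from that sharing. Libraries simulated with counting error and no difference gave at most 1 such tag each. Few tags differ at all in such libraries, so they cannot show what the sharing adds. When the shared library's copies were split at random between the comparisons, part of the count at that lower depth was lost. What remained was 48.8% for the wild type in liquid medium and 73.9% on solid medium. For the deletion strain it was 73.4% in liquid and 74.9% on solid medium.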

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

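The tests in this part were chosen after the patterns had been seen, as was the comparison of medium effects between strains, except that TMM scaling and the comparison of deletion effects were planned, and the limit for the split count against independent lists was set after its value was known.

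Some tags passed the size limits in opposite directions in the 2 media or in the 2 strains. For the deletion effect they numbered 45, with 340 in the same direction, and for the medium effect 30, with 235 in the same direction. The tag CATGACTTCCAGATTTTTATC was among them, with a log2 ratio of deletion strain to wild type of 2.40 in liquid medium and -3.24 on solid medium. Independent lists would give 28.9 and 18.4 tags in the 2 opposite directions for the deletion effect, and 23.5 and 10.8 for the medium effect. Neither total of opposite tags therefore exceeded that of independent lists, but the totals hide a split by direction. For the deletion effect 42 tags were higher in liquid and lower on solid medium, above the 28.9, and 3 went the other way, below the 18.4. The tag named above is among the 42. For the medium effect the observed numbers were 24 and 6. None of the differences between effects was tested, since each effect rests on 1 library per group.

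The media differed at 3.49 times as many tags in the deletion strain as in the wild type, 3794 against 1088. The tables argue against a few technical sources of the whole gap. The ratio of the counts was 3.62 after correction for G and C content, 3.49 without tags 1 base from a far more abundant tag and 3.67 with TMM scaling, where each explanation required at most 1.5. With 1 library per group, variation between cultures cannot be told apart from an effect of the strain, and a single unusual culture could give such a gap. A wider response to the medium without brlA therefore stays an untested hypothesis.

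Tags ending in a run of at least 6 A took 12.7% of the copies in the wild type on solid medium and at most 9.23% elsewhere. A few abundant tags are argued against as its whole source, because without the 20 most abundant such tags the share was 8.65%, against 6.32% in the highest other library. That gap was narrower than with all such tags, so these 20 carried part of it. A change of tag ends at fixed sites is argued against for runs of 4 to 7 A. At each of 923 sites the share of A-ended copies in another library was subtracted from that in the wild type on solid medium. The median of these within-site differences was 0.19 points for the wild type in liquid medium. For the deletion strain it was 0.85 points on solid medium and -0.455 points in liquid medium. A preference for sites close to the poly(A) tail, which may arise in library preparation, stays open: runs of at least 10 A exceeded runs of 6 or 7 A by 0.54 in median log2 ratio against the wild type in liquid medium, but by only 0.16 and 0.14 against the deletion strain in liquid and on solid medium. That source and a real difference in the transcripts of this culture cannot be told apart with 1 library.

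In the wild type on solid medium 327 tags stood above both neighbouring libraries, where independent lists would give 59.0. Counting error in the shared library is not the whole source, since with its copies split between the comparisons 322 tags passed at that lower depth, against 71.5 for independent lists, although the share kept, 73.9% of the unsplit count, fell just short of the 75% set beforehand. Substitutions of 1 base after CATG between strains are argued against, as 0.306% of the tags had a partner 1 base away that was higher in the deletion strain. Other variants, such as a lost CATG site or an inserted base, leave no such partner and were not searched for. Several ends of a site that differ only after the first 14 bases are also argued against, with 270 tags left once tags sharing those bases were merged. Ends that differ within the first 14 bases, such as longer runs of A, were not joined and stay open. Merging A-ended tags alone left 303 and decides nothing, as 262 tags lay outside its reach. The excess was not peculiar to this library, because the deletion libraries gave 759 in liquid and 599 on solid medium. Several CATG sites per gene and an unusual single culture or preparation stay open beside a program of surface growth that depends on brlA. So do the composition of the media and the background of the deletion strain, which are not given. None of these was tested here.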

How the results depend on the processing

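The alternatives for counts above or below both neighbours, the medium effect across strains, the floor of 5 copies, and the settings on neighbouring sequences, merging, G and C content and A-ended tags were chosen after the data were seen. Counts of differing tags are given below in the order deletion strain in liquid medium, deletion strain on solid medium, medium in the wild type, medium in the deletion strain. Counts above both neighbours follow in the order wild type liquid, wild type solid, deletion liquid, deletion solid. With no minimum of copies the counts were 4359, 5490, 2619 and 6943, and 103, 629, 1308 and 940 tags stood above both neighbours. With at least 50 copies they were 886, 1412, 483 and 1733, with 14, 163, 319 and 309 above both. At 2-fold they were 7451, 8916, 4936 and 9853, with 366, 1572, 2555 and 2494 above both. These settings admit more or fewer tags by construction. With the counting interval beyond 2-fold, 903 tags stood above both neighbours in the deletion strain on solid medium. In liquid medium 967 were lower in the deletion strain. Below both neighbours stood 134 in the wild type in liquid medium, 92 in the wild type on solid medium and 196 in the deletion strain in liquid medium. The interval limit replaces both the 4-fold limit and the minimum of copies, so it too admits a different set of tags by construction. Tags below both neighbours, in the library order above, numbered 245, 159, 370 and 759 with no minimum, 29, 24, 32 and 141 with at least 50 copies, and 684, 481, 988 and 1240 at 2-fold. With at least 50 copies in each library the correlation was 0.327 for the deletion effects and 0.282 for the medium effects, from fewer tags. Each of these counts stayed within 1.5 times under TMM and median-of-ratios scaling, a floor of 5 copies, removal of neighbouring sequences, merging of A-ended tags or of tags sharing 14 first bases, correction for G and C content and removal of A-ended tags. The deletion strain led the wild type in the count for the medium under each setting, by between 2.00 and 3.72 times. At 2-fold the share of higher tags among the differing ones was 58.5% in place of 68.8% for the deletion strain in liquid medium, and 51.5% in place of 39.7% for the medium in the deletion strain. A floor of 1 copy cannot change a count, because a tag with 20 copies passes 4-fold at either floor. Not run for want of a reference were totals of gene-assigned tags, sites nearest the 3' end, genes without downstream sequence and the gene lists. No paired analysis was possible because the groups share only 1 replicate number and the counts come from no test. An additive fit of strain and medium over the 4 libraries, which would leave 1 residual degree of freedom, was not run. Leaving out a library would empty its group. Depth limits the rarest tags, as a tag at the floor stands at about 0.5 TPM.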

Other observations

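The values in this part were all looked up after the data had been seen, and no explanation of them was tested.

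The pair of tags CATGTTCTTTCAGAGAAAAAA and CATGTTCTTTCAGAAAAAAAA had similar levels in each library, with 2 and 6 copies in the wild type in liquid medium, 15 and 9 on solid medium, 486 and 511 in the deletion strain in liquid medium and 89 and 80 on solid medium. The pair CATGACGATGCTATGCCAAAA and CATGACGATGCTATGAAAAAA likewise moved together, with 5 and 7 copies in the wild type in liquid medium, 1589 and 1328 on solid medium, 9 and 14 in the deletion strain in liquid medium and 44 and 28 on solid medium. The tags of the former pair differ at 1 base only. Shared first bases, 14 in the former pair and 15 in the latter, do not show by themselves that a pair comes from 1 transcript. The tag CATGAACAGTTAAAAAAAAAA shares 14 bases with CATGAACAGTTAAATTTTCAA, which had 37 and 411 copies in the wild type in liquid and on solid medium and was unlisted in both deletion libraries.

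Tags with at least 20 copies in 1 library and unlisted in the other 3 numbered 41 for the deletion strain on solid medium, 20 for the wild type on solid medium, 14 for the deletion strain in liquid medium and 1 for the wild type in liquid medium, CATGCAGACCCTTCAAAGAGA with 27 copies. The mean G and C content of the bases after CATG, weighted by copies, was 39.1% in the wild type in liquid medium, 38.4% in the wild type on solid medium, 40.4% in the deletion strain in liquid medium and 39.5% in the deletion strain on solid medium. Tags lower on solid medium in the deletion strain averaged 46.2% G and C, against 42.0% for all tags tested in that comparison. Among A-ended tags the median log2 ratio of the wild type on solid to liquid medium was 0.34 for runs of 6 or 7 A, 0.67 for runs of 8 or 9 and 0.88 for runs of at least 10. Against the deletion strain in liquid medium the medians of the wild type on solid medium were 0.56, 0.71 and 0.72 for the same runs, with little rise at the last step. Against the deletion strain on solid medium they were 0.47, 0.73 and 0.61, falling back for the longest runs. Tags ending in 0 to 3 A had medians of 0.04 against the wild type in liquid medium. Against the deletion strain these were 0.05 in liquid and -0.02 on solid medium.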
